A study of Arabidopsis thaliana with 6 samples.

How the data were processed

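Polyadenylated RNA of whole seedlings was measured in 6 libraries, 3 of WT and 3 of 17ab, per the labels. Seedlings were grown on plates for 10 days. The deposited table of each library lists, per gene, a length, an expected count and an FPKM value, per the file headers. The submitters' processing notes name STAR 2.4.0, HTSeq 0.6.0, DESeq2 and the genome build TAIR10, with no role for any of them. The column names are those of an expected count estimator, and which program made the expected counts the authors deposited is not given in the sources used here. The deposited FPKM values are counts scaled by gene length and by the total of the library, per the file headers and as the values show. Between 91.3% and 91.8% of the listed expected counts were whole numbers (tolerance 1e-06), and the rest came from reads divided between genes. Whether strand was used in the counting is not given in the sources used here. Each table lists only genes above 0, so a gene missing from a library was taken as 0 there. Genes listed in at least 1 library numbered 23022, of which 99.2% matched the reference table of TAIR10.1, and all 188 unmatched IDs were organelle genes. That reference differs from the authors' build, so it served for gene names, gene order, GC content and exon length and for upstream sequence, and no coordinates are given.

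The labels do not say whether the libraries came from separate plates or cultures, so that p-values measure the spread between these samples, which may be technical. No pair of libraries was identical, and all 6 were kept as separate samples. Totals of 5968854 to 6292461 put the floor of 3 counts at 0.477 to 0.503 CPM per library. Intervals and floors cover counting error only. Chloroplast genes took 0.012% to 0.016% of the counts, and 0.059% in WT replicate 3.

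Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, with trimmed mean of M-values normalization, the genes kept by its default expression filter (17854, holding 99.78% of the counts) and Benjamini-Hochberg adjustment with a threshold of 0.05. All 6 libraries entered 1 fit with genotype as the single term. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of the F statistic. FPKM values are printed as mean ± SD over 3 libraries. On simulated counts for the same genes, with 200 of them changed, the test recovered 29 of 67 genes changed 1.5-fold, 52 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 11 false calls (7% of calls).

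Before the data were examined, 21 gene lists with 385 genes were written from textbook knowledge: UPR sensors and regulators, ER chaperones and folding enzymes, ER-associated degradation, ER translocation and ER exit, root hair, root identity, photosynthesis, cell cycle, salicylic acid and pathogen response, jasmonate, auxin, cytosolic heat shock, phosphate starvation, iron deficiency, abscisic acid and osmotic stress, expansins and xyloglucan enzymes, flavonoids, seed storage, hypoxia, stomatal lineage and secondary cell wall. Of their genes 377 were listed in at least 1 library. Lists with at least 2 tested members (20) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with camera at an estimated correlation and with fry. On simulated lists camera called 5 of 5 shifted lists and 1 of 15 unchanged lists. The simulated genes were drawn independently, so these rates do not carry over to lists with correlated members. The estimated correlation was 0.472 for phosphate starvation, 0.406 for salicylic acid, 0.174 for jasmonate, 0.054 for cell cycle and 0.0404 for abscisic acid. Fry tests whether a list moves on balance in 1 direction and does not compare it with other genes. None of the 5 camera calls held with an estimated correlation, including those of lists where it was low. These losses are therefore not explained by a high correlation alone.

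The genes named were also fixed by a rule before the data were examined: the 5 stress sensors, the 10 largest rises and 10 largest falls among called protein-coding genes whose groups did not overlap and whose higher group had at least 5 FPKM, and up to 2 risen and 2 fallen members of each list. Chance gives groups that do not overlap in 10% of genes for 3 against 3. Other genes are named as further members of the lists or as said in the text.

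Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, no filter on low counts, a filter of at least 5 CPM in at least 3 libraries, each library left out in turn, the replicate number as a block, DESeq2 1.42.0, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with at least 1 FPKM in at least 3 libraries, no organelle genes, and the estimated correlation. Alternatives chosen after seeing the data were an offset that removes each library's loess trend (span 0.5) on GC content and log length, that offset with the replicate block, and the genes with whole expected counts alone. The 10 splits of the 6 libraries into 3 and 3 were fitted in the same way.

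Product names of the annotation were grouped into 166 classes with at least 10 tested genes, leaving out names without content, joining names that begin with cytochrome P450 in lower case and all ribosomal protein names, and tested with 1-sided Fisher's exact tests against the 17820 tested genes with a product name, in both directions (332 tests, Benjamini-Hochberg). Genes matched to ribosomal protein genes were the 5 nearest others of each on standardized GC content, log length and log mean count. Medians have 95% bootstrap intervals from 10000 draws over genes, which are not independent replicates. Upstream elements were searched on both strands of 500 bases before each gene in TAIR10.1, for 5 elements and 2 gene sets, with 2-sided Fisher's exact tests and Benjamini-Hochberg adjustment over the 10 tests. The deposited gene lengths were tested with limma on log2 length over 6318 genes whose length varied by more than 0.5 bases and whose mean count was at least 50. On simulated lengths that test recovered 57 of 100 genes changed 1.05-fold and 97 of 100 changed 1.2-fold. These steps ran in Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3.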

Results

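Messenger RNA was sequenced from whole Arabidopsis thaliana seedlings, harvested after 10 days on vertical plates, in 3 libraries of wild type (WT) and 3 libraries of a mutant given in the labels as 17ab. The labels name no stress treatment, and seedlings of similar size were picked. The title of the series places the comparison in the unfolded protein response, by which a cell adjusts its gene expression to the load of unfolded protein in the endoplasmic reticulum (ER). The expected counts summed to 6153539, 6198230 and 5968854 in WT replicates 1 to 3 and to 6287122, 6292461 and 6261789 in 17ab replicates 1 to 3. Between 21003 and 21429 genes were listed per library, and the 10 most abundant genes held 5.6% to 6.8% of the counts. Replicates of one group differed by more than sampling noise, with a chi-square per degree of freedom of 2.52 to 4.35 within groups and 7.83 to 10.34 between groups. The first principal component of log2 CPM (counts scaled to the library total) held 47.9% of the variance and separated the genotypes.

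The comparison of 17ab with WT asks how gene expression differs between the genotypes in seedlings with no stress treatment named. The stress sensors of the unfolded protein response were examined first, because the labels do not name the genes mutated in 17ab. Transcripts of 3 of the 5 sensors fell in 17ab. bZIP17 (AT2G40950), a membrane-anchored transcription factor, went from 10.7 ± 0.507 to 2.02 ± 0.104 FPKM (mean ± SD, n = 3), a log2 fold change of -2.43 ± 0.14 (SE, edgeR adjusted p = 1.221e-06). IRE1A (AT2G17520), a kinase and ribonuclease that splices bZIP60 mRNA, went from 12.3 ± 0.247 to 3.93 ± 0.174 FPKM (n = 3), a log2 fold change of -1.68 ± 0.11 (edgeR adjusted p = 2.982e-06). Its paralog IRE1B (AT5G24360) went from 8.09 ± 0.243 to 4.95 ± 0.387 FPKM (n = 3), a log2 fold change of -0.74 ± 0.12 (edgeR adjusted p = 0.001345). The other two sensors did not pass the test: bZIP28 had a log2 fold change of 0.16 ± 0.10 (edgeR adjusted p = 0.3476) and bZIP60 one of 0.23 ± 0.12 (edgeR adjusted p = 0.2574). In the wider list of UPR sensors and regulators, 3 of 11 tested members fell and 1 rose (1 rose and 4 fell adjusted over the list alone). The riser was BI1, an ER membrane protein that counters cell death, at 0.36 ± 0.08 on the log2 scale (edgeR adjusted p = 0.006661). The median of the list was -0.04 and its mean -0.42, with a camera adjusted p of 0.1176 and a fry adjusted p of 0.0004708. The 3 fallen members are the sensors bZIP17, IRE1A and IRE1B given above. The fry call includes them and is no evidence of a wider response apart from those falls.

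**Figure D1:**
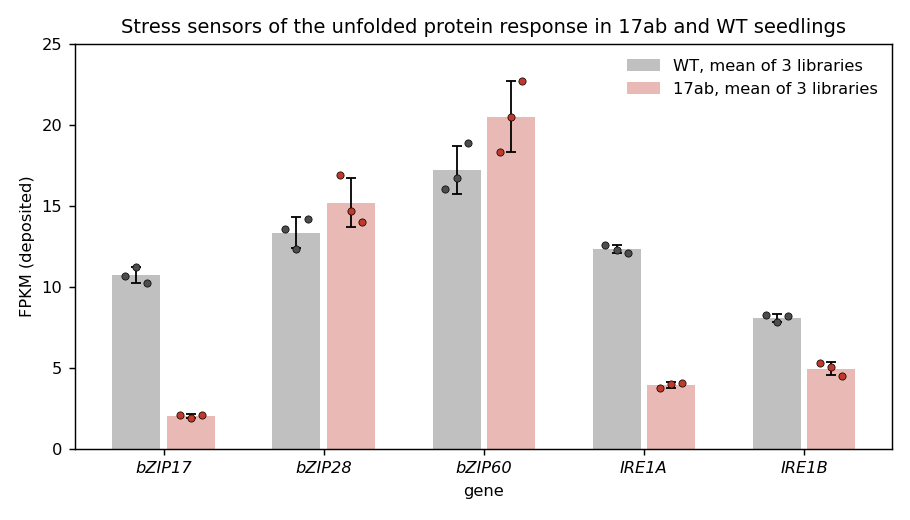
FPKM of the 5 stress sensors (y axis, deposited values) in WT (grey) and 17ab (red), with 1 point per library, bars for the mean of 3 libraries and error bars of 1 SD. bZIP17, IRE1A and IRE1B lie lower in each of the 3 mutant libraries than in any WT library, whereas the ranges of bZIP28 and bZIP60 overlap between genotypes.

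In 17ab 13 of 14 tested phosphate starvation genes rose, as did 16 of 20 jasmonate genes, 7 of 21 genes of salicylic acid and pathogen response and 7 of 17 genes of abscisic acid and osmotic stress, and 9 of 26 cell cycle genes fell. Camera called these 5 lists with its preset correlation and none of them with an estimated correlation (adjusted p from 0.1807 to 0.5149). Of 17854 genes tested, 2515 (14.1%) changed at an edgeR adjusted p under 0.05, of which 1352 rose and 1163 fell. At a change of at least 2-fold the numbers were 342 risen and 45 fallen genes. A setting chosen after seeing the data removed the trend of each library on GC content and gene length. The risen share of all calls then moved from 53.8% to 43.1%, and that of the calls of at least 2-fold from 88.4% to 85.7%. The median log2 fold change of all genes in that fit was -0.038. The change in shares cannot be told apart from this shift of all genes. The count of changed genes was 1571 without WT replicate 2 and 1581 without WT replicate 3. In these fits 12 and 15 of the 56 genes named by rule lost their call. The median log2 fold change of all tested genes was -0.002, and the biological coefficient of variation was 8.4%. Reads had been split between genes in 448 of the calls, 90 of them of at least 2-fold, and these genes are uncertain where a near-identical copy exists.

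The phosphate starvation list rose almost as a whole. Of its 14 tested members, 13 rose (14 adjusted over the list alone), and the median log2 fold change was 1.51. PS2, a phosphatase induced by low phosphate, went from 6.48 ± 1.31 to 34.8 ± 11.9 FPKM (n = 3), a log2 fold change of 2.39 ± 0.23 (edgeR adjusted p = 3.056e-05). The noncoding RNA AT4 (AT5G03545) rose by 2.32 ± 0.20, and IPS1, the RNA that sequesters miR399, by 1.53 ± 0.17 on the log2 scale. Both of these RNAs had reads split with other genes. SPX1 and SPX3, sensors of inositol pyrophosphate, rose by 1.75 ± 0.27 and 2.05 ± 0.40, and SQD2, which makes sulfolipid, rose by 1.07 ± 0.08. The phosphate transporters PHT1;1 and PHT1;4 rose by 1.01 ± 0.17 and 0.87 ± 0.14. The list had a camera adjusted p of 4.607e-12 with a preset correlation, an adjusted p = 0.2165 with an estimated correlation, and a fry adjusted p of 0.006906.

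Jasmonate genes rose from synthesis to response. Of 20 tested members 16 rose (16 adjusted over the list alone), with a median log2 fold change of 0.74. Of the 20, 19 lay above 0, and the lowest, at -1.235, did not pass the test. LOX2, a plastid lipoxygenase, went from 111.5 ± 1.78 to 248.2 ± 27 FPKM (n = 3), a log2 fold change of 1.13 ± 0.08 (edgeR adjusted p = 3.222e-06). The allene oxide cyclase genes AOC2 and AOC3 rose by 1.53 ± 0.10 and 1.85 ± 0.30, and their reads were partly split between copies. OPR3, a reductase in the same pathway, rose by 0.66 ± 0.11, and VSP2, a storage protein induced by jasmonate, by 0.93 ± 0.16. The list had a camera adjusted p of 7.853e-10, an adjusted p = 0.1807 with an estimated correlation, and a fry adjusted p of 0.004247.

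In the list of salicylic acid and pathogen response, 7 of 21 tested members rose and none fell (10 rose adjusted over the list alone), with a median of 0.55. FRK1, a receptor kinase induced by flagellin, rose by 1.47 ± 0.17 (edgeR adjusted p = 0.0001426), and WRKY33, a transcription factor of camalexin synthesis, by 0.88 ± 0.11 (edgeR adjusted p = 0.0001556). PCC1 had the largest rise of the list, 1.82 ± 0.40, with WT libraries that varied widely (9.36 ± 6.88 FPKM, n = 3) and a call that was lost with DESeq2 and with limma-trend on log2(FPKM + 0.1). Without WT replicate 3 the number of risen members was 13, and without 17ab replicate 2 or with DESeq2 it was 4. With limma-trend on log2(FPKM + 0.1) it was 3 of 22 tested. The camera adjusted p was 6.914e-05, with an adjusted p = 0.5149 at an estimated correlation and a fry adjusted p of 0.1611. In the list of abscisic acid and osmotic stress, 7 of 17 tested members rose and none fell (10 rose and 1 fell adjusted over the list alone), with a median of 0.53. KIN2, a cold and drought protein whose reads were partly split, rose by 1.97 ± 0.17, COR15A by 1.82 ± 0.30, and P5CS1, the enzyme of proline synthesis, by 1.44 ± 0.16. That list had a camera adjusted p of 0.0001981, an adjusted p = 0.1807 with an estimated correlation, and a fry adjusted p of 0.004247.

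Of 26 tested cell cycle genes 9 fell, 17 did not pass the test and none rose (14 fell adjusted over the list alone), and the median log2 fold change was -0.36. KNOLLE, the syntaxin of the cell plate, went from 33.9 ± 4.27 to 20.8 ± 2.36 FPKM (n = 3), a log2 fold change of -0.73 ± 0.11 (edgeR adjusted p = 0.0009845). AUR2, an Aurora kinase, had the largest fall of the list, -0.83 ± 0.20, and its call was lost without WT replicate 2, WT replicate 3 or 17ab replicate 2. The mitotic cyclin CYCB1;2 changed by -0.66 ± 0.12, the anaphase activator CDC20.1 by -0.54 ± 0.09 and the cytokinesis kinesin HIK by -0.64 ± 0.11, all past the threshold. The number of fallen members was 5 without WT replicate 2. The list had a camera adjusted p of 2.384e-08, an adjusted p = 0.1807 with an estimated correlation, and a fry adjusted p of 0.005889. Camera with its preset correlation called 5 of 20 lists in the comparison of the genotypes, and 3 to 10 lists in the other 9 splits of the 6 libraries into 3 and 3. Fry called 5 lists in the comparison and 0 in each of those splits. Its 5 lists were not all those of camera. They included the UPR sensors and regulators (fry adjusted p = 0.0004708), where the sensors bZIP17, IRE1A and IRE1B fell. They left out salicylic acid (fry adjusted p = 0.1611). Each of those splits mixes the genotypes in both groups. The genotype difference then widens the spread within groups and remains in part between them, so the splits do not rank camera and fry.

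**Figure D2:**
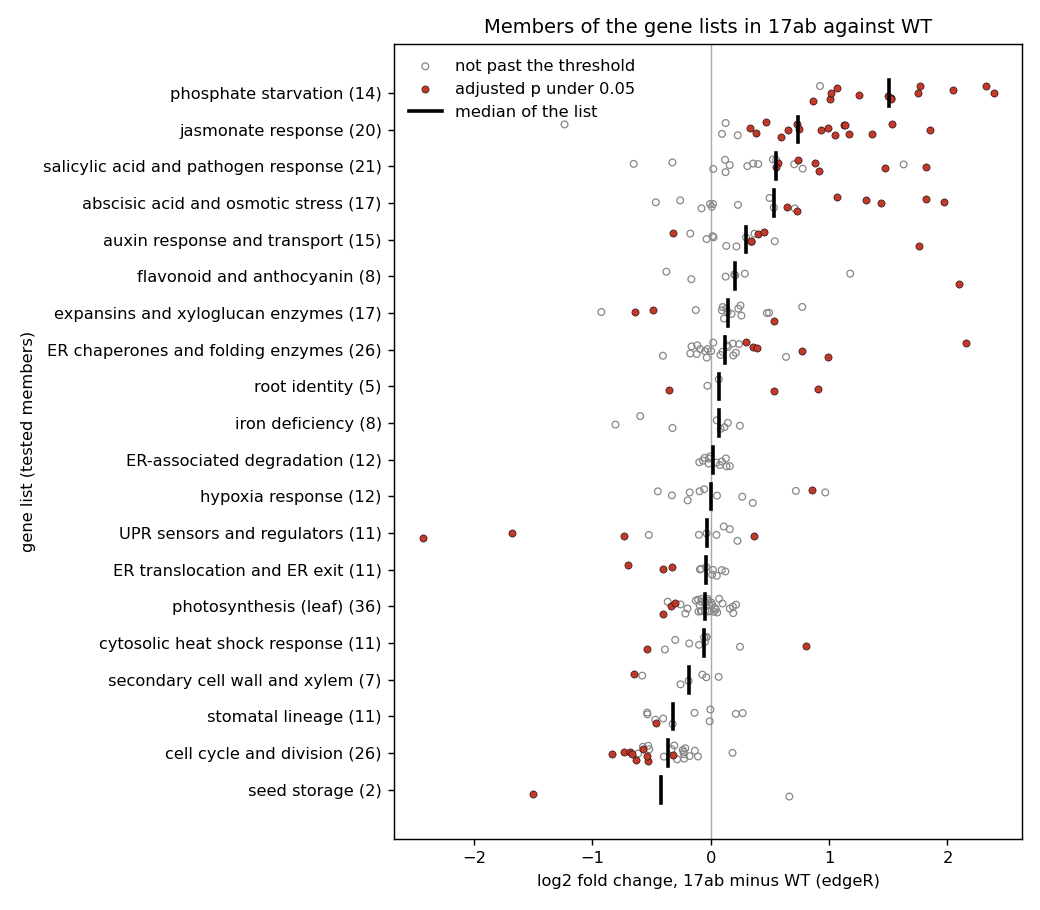
Log2 fold change (x axis, 17ab minus WT, edgeR) of each tested member of the 20 gene lists that had at least 2 tested members (y axis, with the number of tested members), with red points for an adjusted p under 0.05, open points for the rest and a bar for the median of the list. The phosphate starvation list has the highest median, 1.51, and 13 of its 14 members are red, while 9 cell cycle members are red and all to the left of 0.

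ER protein folding genes moved in part. Of 26 tested ER chaperones and folding enzymes 6 rose and none fell (6 adjusted over the list alone), with a median of 0.12 and a camera adjusted p of 0.06173. Without WT replicate 2 only CRT3, BIP3 and PDIL1-3 rose, and without 17ab replicate 3 the list had 4 risen members and 1 fallen, PDIL2-2. Its adjusted p was 0.602 with an estimated correlation, and its fry adjusted p 0.1806. Camera without 1 library gave an adjusted p from 0.007564 to 0.3954, under 0.05 without WT replicate 2 (0.02258), WT replicate 3 (0.007564) or 17ab replicate 2 (0.03451) and highest without WT replicate 1. BIP3, an ER Hsp70 chaperone known for its low level without stress, went from 0.520 ± 0.281 to 2.39 ± 0.645 FPKM (n = 3), a log2 fold change of 2.16 ± 0.39 (edgeR adjusted p = 0.002788). The protein disulfide isomerase PDIL1-3 rose by 0.77 ± 0.09 (edgeR adjusted p = 0.000146), and the J protein ERDJ3A by 0.99 ± 0.23, a call that was lost without WT replicate 2 or 17ab replicate 2. None of the 12 tested members of ER-associated degradation passed the edgeR test, over all genes or adjusted over the list alone, with log2 fold changes from -0.10 to 0.16. In ER translocation and ER exit 3 of 11 fell and none rose (3 adjusted over the list alone): SEC61G1, a small subunit of the translocon, by -0.70 ± 0.11, SAR1B by -0.33 ± 0.08, and SEC61G2 by -0.41 ± 0.13, whose call was lost in 4 of the 6 fits without 1 library.

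In each of the lists for tissues and other pathways 0 to 4 tested members rose and 0 to 3 fell. The leaf photosynthesis list had 3 of 36 tested members past the threshold, RBCS1B, RBCS2B and RBCS3B, near-identical genes of the small subunit of Rubisco that fell by 0.40, 0.30 and 0.34 on the log2 scale. Of the 5 tested root identity genes, the potassium channel gene AKT1 rose by 0.90 ± 0.12 and the phosphate exporter gene PHO1 by 0.53 ± 0.13, while GL2, a repressor of root hair fate, fell by 0.35 ± 0.10, and SHR and SCR, which pattern the root, did not pass the test. A single root hair gene, LRX2, passed the filter on low counts, too few for a set test, and its log2 fold change of -0.44 did not pass the edgeR test. The summed counts of the root hair list were 290 in 17ab and 96 in WT, a ratio of 2.937 (exact 95% interval 2.324 to 3.74, counting error only). Without the filter 4 of 19 root hair genes, PRP3, LRX1, RHS13 and XTH14, rose, and the camera adjusted p of the list was 1.375e-07. Of 15 tested auxin genes 4 rose and 1 fell (6 rose and 1 fell adjusted over the list alone), led by IAA29 at 1.76 ± 0.45, and IAA4 fell by 0.32 ± 0.08. The risen auxin genes numbered 1 without WT replicate 3, 2 without WT replicate 1 or 17ab replicate 3 and 7 without 17ab replicate 1, and the call of IAA4 was lost without WT replicate 2 or 17ab replicate 3. DFR of anthocyanin synthesis rose by 2.1 ± 0.45 as the single call of 8 tested flavonoid genes. Of 17 tested expansin and xyloglucan enzyme genes EXPA4 rose by 0.54 ± 0.10, and XTH22 and XTH9 fell by 0.64 ± 0.19 and 0.48 ± 0.13. Single members passed in the lists of hypoxia (ACO1, risen by 0.85 ± 0.26, 1 of 12 tested, and 3 risen and 1 fallen adjusted over the list alone), the stomatal lineage (TMM, at -0.46 ± 0.10, 1 of 11 tested, and 2 adjusted over the list alone, with a list median of -0.32), the secondary cell wall (LAC4, at -0.65 ± 0.14, 1 of 7 tested, and 2 adjusted over the list alone) and seed storage (CRA1, at -1.5 ± 0.38, 1 of 2 tested). In the cytosolic heat shock response HSFB1 rose by 0.81 ± 0.19 and HSFA7A fell by 0.54 ± 0.16, of 11 tested (1 rose and 2 fell adjusted over the list alone). None of the 8 tested iron deficiency genes passed the edgeR test, over all genes or adjusted over the list alone. The calls of GL2, PHO1, IAA29, IAA4, XTH22, XTH9, ACO1, HSFB1, HSFA7A, CRA1 and RBCS3B were each lost in at least 1 of the fits without 1 library. Without 1 library other members passed, with 5 fallen photosynthesis genes without 17ab replicate 2 and 1 risen without WT replicate 1, 3 risen expansin and xyloglucan enzyme genes without WT replicate 2 and 2 without WT replicate 1 or 3, and 2 fallen secondary wall genes without WT replicate 3. Of the iron deficiency genes bHLH100 and bHLH39 fell without 17ab replicate 1 and BTS rose without 17ab replicate 2, where FLS1 of the flavonoids and LBD41 of the hypoxia list also fell. These 5 genes, like CRT3 and PDIL2-2, were named after their values were seen. None of the lists in this paragraph had a camera adjusted p under 0.05 with all 6 libraries and the filter on low counts, while without the filter it was 0.02812 for flavonoids and 0.03763 for the stomatal lineage. With an estimated correlation, all 6 libraries and the filter, it ran from 0.395 for the stomatal lineage to 0.8271 for photosynthesis and iron deficiency. The estimated correlation was not used without the filter or without 1 library. Without WT replicate 2 the camera adjusted p was 0.0215 for photosynthesis, 0.02258 for auxin and 0.01521 for expansins and xyloglucan enzymes, without WT replicate 3 it was 0.007721 for the secondary wall, without 17ab replicate 1 it was 0.003823 for auxin, without 17ab replicate 2 it was 0.04374 for photosynthesis and 0.04129 for the stomatal lineage, and without WT replicate 1 it was 0.04944 for the stomatal lineage.

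Among called protein-coding genes with at least 5 FPKM in the higher group and no overlap between the groups, the largest rises were those of ATC, AT5G06645, MRD1, BGLU22, BGLU21, TH8, HEI10, GolS2, OSM34 and AT3G22235. ATC (AT2G27550), of the family of the flowering repressor TFL1, went from 0.17 ± 0.17 to 7.24 ± 0.876 FPKM (n = 3), a log2 fold change of 5.25 ± 0.48 (edgeR adjusted p = 2.263e-05). MRD1 (AT1G53480) rose by 4.3 ± 0.25 and its neighbour HEI10 (AT1G53490), known from meiotic crossovers, by 3.0 ± 0.22, and the pair overlaps in the annotation, so that their reads cannot be told apart without knowledge of strand. The beta-glucosidase genes BGLU22 and BGLU21, also neighbours, rose by 4.28 ± 0.58 and 3.23 ± 0.45 with reads split between them or others. BGLU22 had 14.65, 4.78 and 4.41 FPKM in 17ab replicates 1 to 3, and 0.26 to 0.47 FPKM in WT. GolS2, a galactinol synthase, rose by 2.73 ± 0.35 and the osmotin-like gene OSM34 by 2.70 ± 0.34. AT3G22235 reached 513.4 ± 162 FPKM in 17ab against 80.2 ± 56.3 in WT (n = 3). Reads of AT3G22235, a neighbour of PCC1, and of AT5G06645 were also partly split with other genes. Besides bZIP17 and IRE1A, the largest falls under the same limits were those of SWEET10, AT3G11591, SEP3, AT1G06080, AT4G15700, PHI-1, CGA1 and AT1G16916. SWEET10, a sugar transporter, went from 12.2 ± 3.2 to 2.52 ± 0.905 FPKM (n = 3), a log2 fold change of -2.29 ± 0.27 (edgeR adjusted p = 0.0001446), and SEP3, a MADS-domain factor of flower development, from 23.3 ± 0.416 to 7.76 ± 1.19 FPKM (n = 3), a log2 fold change of -1.60 ± 0.13 (edgeR adjusted p = 1.095e-05). PHI-1 changed by -1.20 ± 0.18 and CGA1, a GATA factor of chloroplast development, by -1.16 ± 0.24. The calls of AT3G11591, AT4G15700 and AT1G16916 were lost in 4 or 5 of the 6 fits without 1 library.

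Ribosomal protein genes were enriched among the fallen genes. Product names of the annotation were tested for enrichment among the calls, a step chosen after the gene results were seen. Of 309 tested genes named as ribosomal proteins 177 fell (57.3%, against 6.5% of all tested genes with a product name) and none rose, with a Fisher's exact test adjusted p of 7.194e-127 over 332 tests that treat genes as independent. Their median log2 fold change was -0.30, a fold of 0.814, and 278 of the 309 lay below 0. None of them fell at least 2-fold. The class was drawn by product name and includes eEF-1Bb1, a translation elongation factor. PGY1, a protein of the cytosolic large subunit whose reads were partly split, changed by -0.42 ± 0.06, RPL24A of the same subunit by -0.42 ± 0.07, and PRPL11 of the plastid ribosome by -0.38 ± 0.06, all past the threshold. These genes took 4.70%, 4.96% and 4.97% of the counts in WT replicates 1 to 3 and 4.12%, 3.93% and 4.03% in 17ab replicates 1 to 3. The class had a negative median in every alternative fit, from -0.31 to -0.27, with at most 1 risen gene, and the number of fallen genes was 115 without WT replicate 3 and 110 of 204 among genes with whole expected counts alone. Of 27 tested histone genes 7 fell (Fisher's exact test adjusted p = 0.04568), but 3 without WT replicate 2, 3 without WT replicate 3 and 4 without 17ab replicate 1. Among genes with whole expected counts alone, 2 of 11 tested histone genes fell.

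**Figure D3:**
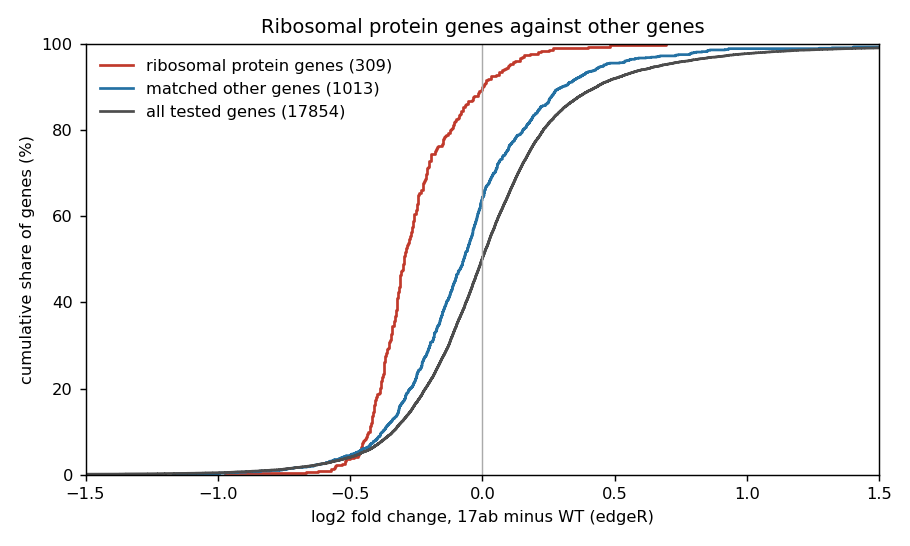
Cumulative share of genes in percent (y axis) by log2 fold change (x axis, 17ab minus WT, edgeR) for 309 ribosomal protein genes, 1013 other genes matched to them on GC content, length and mean count, and all 17854 tested genes, with the x axis limited to 1.5 on each side. The curve of the ribosomal protein genes lies to the left, with a median of -0.30 against -0.07 for the matched genes and -0.002 for all.

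Among the risen genes, cytochrome P450 genes (29 of 108 tested, Fisher's exact test adjusted p = 1.916e-07), peroxidase superfamily genes (14 of 31, adjusted p = 1.667e-06) and berberine bridge enzyme-like genes (9 of 17, adjusted p = 9.304e-05) were enriched. A separate class named as cytochrome P450 superfamily had 2 of 13 risen and was not enriched. The peroxidase class includes DOX1, an alpha-dioxygenase, and had 9 risen members without WT replicate 3. CYP83B1 and CYP79B2, enzymes of indole glucosinolate synthesis, rose by 0.89 ± 0.09 and 0.57 ± 0.11, and CYP81F2, which modifies indole glucosinolates, by 1.33 ± 0.16. PRXR1, an abundant peroxidase, went from 850.9 ± 21.4 to 1474 ± 23.3 FPKM (n = 3), a log2 fold change of 0.77 ± 0.06 (edgeR adjusted p = 9.858e-06). The berberine bridge enzyme-like gene AT2G34810 rose by 1.48 ± 0.14. Genes of lipid-transfer proteins (12 of 35), 2-oxoglutarate-dependent oxygenases (15 of 61), S-locus lectin kinases (7 of 15) and 2 classes of leucine-rich repeat proteins (11 of 40 and 7 of 22) were the other enriched classes of risen genes, with adjusted p from 0.000368 to 0.03232. In the lipid-transfer class 4 of 35 genes fell, among them DIR1 by 0.88 ± 0.10. The risen genes of these 5 classes were fewer whichever library was left out, as were all calls (1571 to 2090, against 2515 with 6 libraries). Their median log2 fold changes stayed above 0 in these fits. The berberine bridge enzyme-like class had 6 risen genes without WT replicate 3. The risen lipid-transfer genes numbered 6 without 17ab replicate 1 and 7 in each of the other fits without 1 library, and the oxygenases 9 without WT replicate 1 or 2. The S-locus lectin kinases numbered 3 without WT replicate 2 and 4 without 17ab replicate 3, and the larger leucine-rich repeat class 5 without WT replicate 2 and 6 without WT replicate 3 or 17ab replicate 3. The smaller one numbered 3 without WT replicate 1, WT replicate 3 or 17ab replicate 3 and 4 without 17ab replicate 2, and had 4 risen and 2 fallen genes with the GC and length trend removed. Enrichment was not tested again in these fits. The genes named in this paragraph, like PGY1, RPL24A and PRPL11, were chosen as examples after their values were seen.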

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

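The GC and length offset, alone and with the block, and the restriction to whole expected counts were chosen after seeing the data. No gene called in the comparison changed sign in any alternative fit. The main counts were 2515 changed, 1352 risen and 1163 fallen genes, and 387, 342 and 45 at 2-fold. Of 102 alternative counts of changed genes 87 stayed within 1.5 times the main count. Without 1 library, changed genes numbered 1571 to 2090, lowest without WT replicate 2. In the same fits risen genes ranged from 889 to 1137, fallen genes from 643 to 953. With DESeq2 1599 genes changed, 872 up and 727 down. Fallen genes numbered 770 with limma-trend on log2(FPKM + 1) and 726 on log2(FPKM + 0.1). With at least 5 CPM in at least 3 libraries fewer genes were tested, and 227 changed at least 2-fold, 206 up and 21 down. Without a filter 75 genes fell at least 2-fold, since more genes were tested. Except for the last 2 settings, whose construction explains them, the cause was not tested. The replicate numbers do not pair the libraries: deviations from the group means correlated at -0.003, -0.108 and -0.046 between libraries of the same number. With a replicate block 1853 genes changed, 351 at least 2-fold, and 6 named genes were no longer called. With the block and the GC and length offset 872 genes rose.

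Of 56 named genes 37 kept their side of the threshold in each of the 17 alternative fits that tested them, and of 259 alternative list tests 241 kept theirs. Depth and number of libraries limit small changes, with 29 of 67 simulated changes of 1.5-fold recovered. The simulation changed 200 genes, against 2515 called in the data. The adjusted threshold depends on the share of changed genes, so recovery in the data may differ. With an estimated correlation the camera adjusted p was 0.2165 for phosphate starvation, 0.1807 for jasmonate response, cell cycle and abscisic acid, and 0.5149 for salicylic acid. Without a filter, flavonoid (0.02812) and stomatal lineage (0.03763) were called by camera, and so was root hair (1.375e-07), which has no set test with the filter and ranged from 0.04573 to 0.2909 in 5 fits without 1 library. Over the 6 fits without 1 library the camera adjusted p ranged from 0.007564 to 0.3954 for ER chaperones, 0.0215 to 0.6988 for photosynthesis, 0.003823 to 0.1842 for auxin, 0.01521 to 0.3383 for expansins, 0.007721 to 0.2509 for the secondary wall and 0.04129 to 0.1324 for the stomatal lineage. The cause was not tested.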

Other observations

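The sulfur and flowering genes, the product classes, the deposited lengths and the tests of whole root share, of dividing tissue, of neighbours with whole counts and of neighbours by chromosome were chosen after the results they concern were seen. Of 5 further groups of genes looked at by eye (clock, sulfur, root, flowering and copper), sulfur and flowering are described. The other groups are given no counts, and enrichment was not tested for any of the 5. Of all 17854 tested genes 1352 rose and 1163 fell. Of 14 tested genes known from sulfur deficiency 11 rose in 17ab and none fell by the edgeR test. LSU1 went from 4.96 ± 0.567 to 28.2 ± 9.15 FPKM (n = 3), a log2 fold change of 2.43 ± 0.27 (edgeR adjusted p = 0.00011). SDI1 rose by 2.05 ± 0.20, BGLU28, a beta-glucosidase, by 1.54 ± 0.19 and the sulfate transporter SULTR1;2 by 0.82 ± 0.15 on the log2 scale. The APS reductase genes APR1 and APR3 rose by 0.53 ± 0.08 and 0.45 ± 0.07, whereas APR2 had a log2 fold change of -0.06, SDI2 one of -0.20 and SULTR2;1 one of -0.11, none past the threshold. The call of LSU2 (0.80 ± 0.23) was lost in 5 and that of GGCT2;1 (1.08 ± 0.26) in 3 of the 6 fits without 1 library.

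Of 6 tested genes of flowering and phase change 5 fell. FT, the mobile signal of flowering, went from 17.3 ± 6.05 to 8.41 ± 2.55 FPKM (n = 3), a log2 fold change of -1.07 ± 0.26 (edgeR adjusted p = 0.01408), and its call was lost without WT replicate 2, where the adjusted p was 0.07426. SEP3 fell as given above, in every alternative fit. SOC1 (-0.36 ± 0.11), SPL3 (-0.55 ± 0.15) and SPL9 (-0.67 ± 0.21) passed the threshold and were lost in 5, 4 and 6 of the 6 fits without 1 library. FLC, a repressor of flowering, had a log2 fold change of -0.28 ± 0.36 (edgeR adjusted p = 0.6811).

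The comparison of the genotypes gave 2515 changed genes, 387 of them at least 2-fold, and 1 of the 10 splits of the 6 libraries into 3 and 3, the comparison itself, gave as many, with 0 as the highest other value for both. For the gene lists 8 of the 10 splits gave as many camera calls, with 5 in the comparison and 10 as the highest other value. For the deposited gene lengths all 10 splits gave as many, since limma called 0 of 6318 genes in the comparison (444 at an unadjusted p under 0.05) and 0 as the highest other value. With 10 splits a share under 0.05 cannot be reached. The other splits mix the genotypes in both groups, which widens the spread within groups, so that 0 changed genes there were likely in advance.

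Ribosomal protein genes were lower in 17ab, with a median log2 fold change of -0.30 (95% bootstrap interval -0.31 to -0.27). A bias of GC content or gene length is argued against by 1013 other genes matched on GC content, length and mean count, whose median was -0.071 (-0.092 to -0.053). With the GC and length trend removed, the median of the ribosomal protein genes was -0.29. A smaller share of dividing tissue in the 17ab libraries stays open, because the cell cycle list had a median of -0.362 (-0.552 to -0.237) and the intervals overlap. An effect of the genotype on ribosomal protein genes within cells is a hypothesis that cannot be told apart from it here, since whole seedlings were measured.

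The phosphate starvation list was higher in 17ab, with a median rise of 2.84-fold, as were the summed counts of the root hair list, 145, 84 and 61 in 17ab against 22, 38 and 36 in WT. With the GC and length trend removed the phosphate list had a median log2 fold change of 1.475, which argues against such a bias for that list. A larger share of whole root in 17ab stays open for both, and was not tested for the other risen genes and product classes. In WT replicates 1 to 3 the root hair list summed to 3.58, 6.13 and 6.03 CPM. The summed markers of endodermis, root cap and root meristem (ratio 1.03, exact 95% interval 0.689 to 1.54) rest on 54 and 51 counts over 10 genes, near the floor. The 5 tested root identity genes had a median log2 fold change of 0.07 and went both ways. AKT1 and PHO1 rose, GL2 fell, and SHR and SCR did not pass the test. Outside the list, 65 of 329 genes that rose at least 2-fold (19.8%) carried the P1BS element, bound by the phosphate starvation regulator PHR1, within 500 bases upstream, against 1582 of 15296 unchanged genes (10.3%), an odds ratio of 2.134 (95% interval 1.593 to 2.825, Fisher's exact test adjusted p = 6.451e-06). This is consistent with a phosphate starvation response in 17ab, a hypothesis.

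Genes that rose at least 2-fold lay beside each other in 37 pairs, against a mean of 6.62 in shuffled gene orders (permutation p = 0.0001, the smallest that 10000 shuffles can give), and none of the pairs fell. Shared or overlapping reads may account for part of them, since only 10 of the 37 pairs had whole counts in every library and no overlap in the annotation. Whole counts and no overlap argue against shared reads for these 10. They exceeded a mean of 3.4 in shuffled orders (permutation p = 0.0023), which bears on whether such pairs cluster and not on shared reads. These 10 include CYP705A5, CYP708A2 and THAS1 of thalianol synthesis, LSU1 with LSU3, and COR15A with COR15B. Position argues against variants linked to the mutated loci, taken as bZIP17, IRE1A and IRE1B, for the 25 pairs on chromosomes without these loci. These 25 exceeded a mean of 4.04 in shuffled orders (permutation p = 0.0001, again the smallest possible), which does not bear on linkage. Most of them had split reads or overlapped, so shared reads stay open for those. Only AT3G21770 with UGT71B6, LSU3 with LSU1 and CRK14 with CRK15 were free of both limits. The thalianol and COR15 pairs lie on chromosomes that carry a locus. Linked variants stay open for the other 12 pairs, of which 0 lie within 50 tested genes of a locus, because such variants can lie farther off. In that window 9 of 300 genes changed at least 2-fold, against a median of 6 at random positions (permutation p = 0.2259). Duplication of genes with shared regulation was not tested.

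As a hypothesis, ER stress elements could be more frequent upstream of genes that fell. The element with the smallest p, UPRE, was found upstream of 46 of 1160 fallen genes (4.0%) and 2.9% of unchanged genes, an odds ratio of 1.369 (95% interval 0.9815 to 1.869, Fisher's exact test adjusted p = 0.2096), which leaves the hypothesis open. The other ER stress elements had odds ratios under 1, 0.4811 (0.09706 to 1.46) for ERSE-I and 0.7755 (0.01854 to 4.958) for ERSE-II.

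BG3, a glucanase gene, had 62 counts in 17ab and 0 in WT, at least 20-fold higher with a floor of 3 counts over the group. AT1G21651, with split reads, had 0 counts in 17ab and 40 in WT, at least 13.7-fold lower with the same floor.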
